A study of Mus musculus with 2 samples.

How the data were processed

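Intestinal cells of Lgr5-GFP mice were sorted by flow cytometry into Lgr5-positive and Lgr5-negative fractions, with 1 library each. Per the labels' protocols, total RNA was depleted of ribosomal RNA, treated with RNase R, which digests linear RNA, fragmented to about 200 bp and sequenced as paired reads of 150 nt. The submitters' processing notes name Trimmomatic 0.36, FastQC and the build mm9. The aligner and the circRNA caller are not given in the sources used here.

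For each library the authors deposited a list of circRNAs with chromosome, start, end and host gene, and 3 values per circRNA. Per the file headers these are a count, an RPM value and a junction count. The deposited count is a whole number of reads assigned to the circRNA, and how it was assigned is not given in the sources used here. The deposited RPM value is that count scaled to 1000000 reads, and dividing the one by the other gives library totals of 52636694 reads for the label ISC and 72271995 for the label non-ISC. The junction count of the authors holds reads across the back-splice junction, and it was the measure used here. It equalled the count for 42.3% and 33.3% of entries. No column holds reads of the linear transcript, so no circular to linear ratio was computed.

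The junction ends were compared with GENCODE release M21 on GRCm38. Starts fell exactly on exon starts for 79.4% and 76.6% of circRNAs of the respective libraries and ends on exon ends for 79.6% and 76.5%, against at most 0.344% when shifted by 1 nt. The coordinates are therefore given as GRCm38, counted from 1, although the notes name mm9. Of 8174 host gene symbols, 7305 are in that release. A further 491 names are of FANTOM transcripts, so that 1 locus can be split over 2 names. Host genes are named as the files name them, and exon numbers follow the basic protein-coding transcript with the lowest name that has both ends.

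The total of junction reads was 156582 and 76331, so that 3 counts, taken as the limit of a count of 0, come to 19.2 and 39.3 per 1000000 junction reads. A circRNA without an entry in a library was counted as 0. Of the entries labelled non-ISC, 6122 had 0 junction reads, and of those labelled ISC none. Abundant circRNAs can lack an entry where other circRNAs of the host gene have one, so a missing entry need not be 0 reads. For this reason single circRNAs against a missing entry are given as reads, with no fold. Ratios of host genes and gene lists count missing entries as 0 and share this limit.

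Ratios are of reads divided by each library's total, with exact conditional (Clopper-Pearson) intervals at 95%. A circRNA or host gene counts as higher or lower with at least 10 reads over both libraries, a ratio of at least 2 in either direction and an interval excluding 1. Shares have exact binomial intervals. Numbers higher and lower were set beside 100 seeded draws of both libraries from 1 common profile. Fragments of about 200 bp read over 150 nt from each end can cross a junction with both mates, so intervals may be too narrow, and the draws were repeated with reads in pairs. On simulated libraries 200 of 31496 listed circRNAs were changed, all picked from those expected to have at least 10 reads over both libraries. Of the 31496, 26265 had a junction read in the real libraries. The rule recovered 19.4% of 2-fold, 70.1% of 4-fold and 93.9% of 8-fold changes, and called 2.46% of unchanged circRNAs with enough reads. For 7256 host genes, changed by the same choice, the shares were 32.8%, 86.6% and 98.5%, and 2.30%. The recovered shares do not hold for circRNAs or host genes with fewer reads. These simulations drew single reads, so the shares do not hold where both mates were counted. Draws from 1 common profile gave medians of 43 higher and 44 lower circRNAs with single reads, and 247.5 and 182 with reads in pairs.

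Before the data were examined, 19 gene lists were fixed: Lgr5 stem cell signature, reserve stem cell markers, enterocyte, goblet and Paneth, enteroendocrine, tuft, immune cells, stromal with muscle and endothelial, the Wnt, Notch, BMP with TGF-beta and Hippo pathways, the IL-13 receptor axis with Foxp1, cell cycle, chromatin regulators, ubiquitin ligases, RNA binding, widely abundant hosts, and epithelial junction. A gene in more than 1 list counts in each. For each list the reads were summed over its members, and the median log2 ratio of members with at least 10 reads (pseudocount 0.5 read) was placed among 10000 random lists matched in 10 level bins. For 15 lists there were enough members. Percentiles describe these libraries, since genes are not replicates. After the data were seen, 7 lists were added, each written before its own values were looked at: T lineage, B lineage, myeloid, thymocyte, cytotoxic T and NK, epithelial transcription factors, and keratin with adhesion of epithelium.

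The genes named follow a rule fixed with the lists: the 5 most abundant circRNAs of each library; per direction the 10 circRNAs and 5 host genes whose interval bound nearest 1 lies farthest from it; per list up to 4 members with the most reads and up to 4 more that are higher or lower; and circRNAs of Pan3. Lgr5 is given as the gene of the sort. Examples beyond these bounds, such as Tox, Yap1, Cd160 and the genes with an exchanged leading circRNA, were chosen after their values were seen. Alternatives were other scalings (median ratio, total without the 10 most abundant, TMM), minimums of 0, 5 and 20 reads, folds of 1.5 and 4, a 99% interval, circRNAs with reads in both libraries, and changes to lists, matching and minimums for shares. Scaling to library totals, halved reads, lists over circRNAs with reads in both libraries and added lists without each member in turn were chosen after seeing the data. Some items that the rule names are not reported here. Leaving out a library was not possible with 1 per group. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.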

Results

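Circular RNAs (circRNAs) are closed RNA molecules made when a splice donor is joined to an upstream acceptor, and a read across that back-splice junction marks them. They were profiled by sequencing in intestinal cells of Lgr5-GFP reporter mice aged 2 months, sorted into an Lgr5-positive fraction, labelled ISC for intestinal stem cells, and an Lgr5-negative fraction, labelled non-ISC. Each group had 1 library, so no difference given here has a replicate check and no p-value is given. The library labelled ISC held 156582 junction reads on 18438 circRNAs from 5823 host genes. The library labelled non-ISC held 76331 junction reads on 12202 circRNAs from 4823 host genes. Per 1000000 reads of the library totals implied by the deposited RPM values, these were 2975 and 1056 junction reads. Which reads those totals count is not given. Ratios below are shares of each library's junction reads, labelled ISC over labelled non-ISC, with 95% exact counting intervals. These intervals cover counting error only, and they compare these libraries, not the cell types.

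The gene used for the sort had too few reads for the 10-read rule, and its signature went against the labels. Lgr5, the Wnt target that marks crypt base stem cells, had no circRNA reads in the library labelled ISC and 7 in the library labelled non-ISC. Of 28 genes in the Lgr5 stem cell signature, 17 had a circRNA and 8 had at least 10 reads, of which 6 were lower and 0 higher in the library labelled ISC. Prom1 had 0 reads against 50, Smoc2 had 0 against 45 and Slc12a2 had 0 against 26, in the order labelled ISC and labelled non-ISC. Axin2, a feedback inhibitor of Wnt signalling, had 10 reads against 29, a ratio of 0.168 (0.0731 to 0.355). Znrf3 had 23 against 12, a ratio of 0.934 (0.446 to 2.06). Summed over the list the ratio was 0.145 (0.109 to 0.192), or 0.307 over circRNAs with reads in both libraries, and the list's median lay at percentile 0.01 of 10000 random lists of the same size and level. Because of this the groups are named below by their labels, and every direction is one between libraries as labelled. The reserve stem cell list could not be scored, as Lrig1 alone had reads, 0 against 6. Epithelial junction and polarity genes, given below, had a summed ratio of 0.105, so the low signature is not particular to stem cell genes.

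The first comparison asked which circRNAs the fractions share. Of 26265 circRNAs with a read in either library, 4375 (16.7%, 16.2 to 17.1) had reads in both, and these held 66.9% of the reads of the library labelled ISC and 62.9% of those of the library labelled non-ISC. Most entries were thinly covered: 54.6% and 57.3% of the circRNAs of the respective libraries had 1 or 2 reads. Among the 3659 circRNAs with at least 10 reads over both libraries, 2542 (69.5%) were in both. Thinned to the reads of the shallower library, the library labelled ISC held 14274 circRNAs (median of 100 draws, range 14171 to 14361). Single reads were drawn here, so where both mates of a pair were counted this number would be too high. Thinning with reads in pairs was not done. An exonic circRNA of Rasa2, a Ras GTPase-activating gene, was among the 5 most abundant in each library (chromosome 9, 96602713 to 96611499, exons 2 to 4). It had 1148 reads against 584, a ratio of 0.958 (0.867 to 1.06).

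The second comparison asked which circRNAs and host genes differed. Satb1, which encodes a chromatin organiser known from thymocytes, led the library labelled ISC, and Btnl1, a butyrophilin-like gene of intestinal epithelium, led the library labelled non-ISC. The Satb1 circRNA of exons 2 to 5 (chromosome 17, 51803431 to 51809287) had 3462 reads against 3, a ratio of 563 (192 to 2729). The Btnl1 circRNA of exons 4 to 8 (chromosome 17, 34380961 to 34382488) had 2258 reads in the library labelled non-ISC and none listed in the other. With at least 10 reads, a ratio of at least 2 in either direction and an interval excluding 1, 1187 circRNAs were higher and 841 lower in the library labelled ISC. Draws of both libraries from 1 common profile gave at most 113 in all, or 487 where reads were drawn in pairs. Of these, 789 higher and 328 lower circRNAs had no reads in the other library, and among circRNAs with reads in both there were 398 higher and 513 lower. Scaled to library totals in place of junction reads, every log2 ratio moves up by 1.49, ratios between 0.355 and 1 turn above 1, and the split becomes 2140 higher and 426 lower. With junction reads halved, as if both mates of each pair had been counted, it was 472 and 355.

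**Figure D1:**
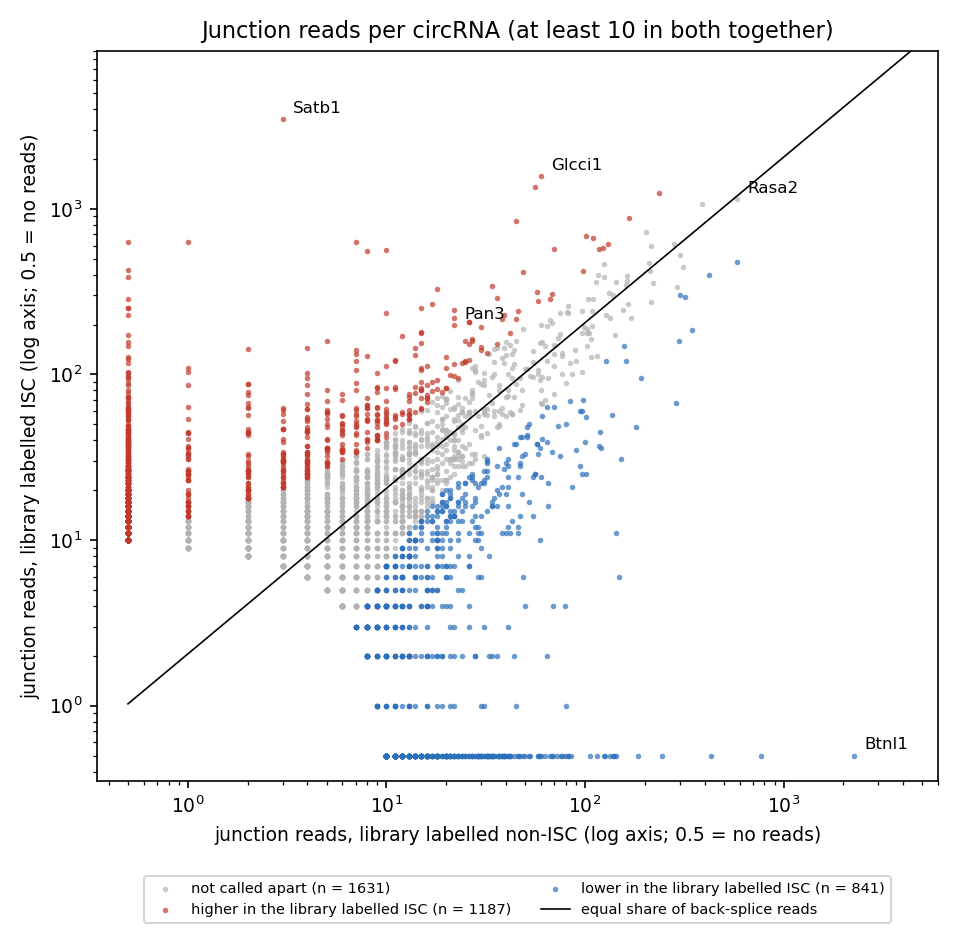
Junction reads per circRNA in the library labelled non-ISC (horizontal, log axis) and the library labelled ISC (vertical, log axis), for the 3659 circRNAs with at least 10 reads over both; 0.5 stands for no reads. Red points are the 1187 higher and blue points the 841 lower in the library labelled ISC, and the line marks an equal share of each library's reads.

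The single-exon circRNA of Themis, needed for thymocyte selection, also led the library labelled ISC, with 634 reads against 1, a ratio of 309 (55.3 to 12226). A circRNA of exons 2 to 9 of Satb1 had 426 reads, a Camk4 circRNA 251, an Epsti1 circRNA 285 and one of the non-coding gene 2610307P16Rik 253, all with none listed in the library labelled non-ISC. CircRNAs of Lbr (389 reads), Arl8b (230), Zfp426 (174) and the mitotic checkpoint gene Bub1b (630) likewise had none there. For Bub1b, Arl8b and Lbr the host gene did have other circRNAs in the library labelled non-ISC, with 55, 11 and 5 reads. Glcci1 gave 2 of the 5 most abundant circRNAs, with 1576 reads against 60 (ratio 12.8, 9.89 to 16.9) and 1345 against 56 (ratio 11.7, 8.96 to 15.6). Erbb2ip, annotated as Erbin, had 1245 against 235, a ratio of 2.58 (2.25 to 2.98). By host gene sums Satb1 (4292 reads against 3), Themis (784 against 2), 2610307P16Rik (390 against 0), Epsti1 (340 against 0) and Camk4 (286 against 0) led.

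In the other direction the leading circRNAs came from host genes without and with other reads in the library labelled ISC. Btnl1, Cdhr2, Atp9a and BC021891 (annotated as Map3k21) had no circRNA reads there at all. Their leading circRNAs had 2258, 140, 133 and 143 reads in the library labelled non-ISC. By host gene sums Btnl1 (2421 reads), Atp9a (196), Heph (185), BC021891 (169) and Cdhr2 (160) led, each against 0. CircRNAs of Gigyf2 (770 reads), Zfp827 (430), Tns3 (245), Rnf169 (185), Rad52 (139) and Usp3 (126) had none listed in the library labelled ISC, but their host genes had 28, 66, 74, 39, 29 and 87 reads there on other circRNAs. Whether those entries stand for 0 reads is open, so no fold is given for them. A circRNA that the files place in Rbm4 (chromosome 19, 4792398 to 4794009), with ends on exons of different transcripts, had 477 reads against 583, a ratio of 0.399 (0.353 to 0.451) that turned to 1.12 when scaled to library totals. Over host genes, 779 were higher and 663 lower of 2920 with at least 10 reads, against at most 80 by chance (322 with paired reads) and a split of 1717 and 324 with library totals.

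Host genes of intestinal epithelium were low in the library labelled ISC. All 10 enterocyte genes with at least 10 reads were lower there. Among them were Cdhr2, a brush border protocadherin (0 reads against 160), the glucose transporter gene Slc5a1 (0 against 56) and the digestive enzyme genes Mgam (0 against 48) and Enpep (4 against 35). Over 28 enterocyte genes with a circRNA the summed ratio was 0.0159 (0.00901 to 0.0261). The 3 goblet and Paneth genes with enough reads were also lower (Fcgbp, 0 against 25; Zg16, 0 against 21; Kit, 2 against 8), with a summed ratio of 0.0225 (0.00452 to 0.0687). Enteroendocrine genes gave 0.0488 (0.00552 to 0.201), with Cacna1a at 2 against 11, and tuft genes 0.188 (0.0807 to 0.402), with Plcg2 at 0 against 18. Of 19 epithelial junction and polarity genes, 17 were lower and 0 higher. Epcam, the pan-epithelial adhesion gene, had 0 reads against 59, Pkp2 had 0 against 73, Myo5b had 2 against 87 and Magi3 had 42 against 31. The summed ratio of that list was 0.105 (0.0869 to 0.126). The enterocyte, goblet and Paneth, and junction lists lay at percentiles 0, 0.34 and 0 of random lists. Restricted to circRNAs with reads in both libraries, the junction list's ratio was 0.240. No circRNA of the enterocyte or the goblet and Paneth list had reads in both libraries. The ratios of these lists therefore rest on missing entries counted as 0.

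Host genes of immune cells were high in the library labelled ISC. Of 18 with at least 10 reads, 14 were higher and 0 lower, and the summed ratio was 7.36 (6.39 to 8.52) at percentile 100. Bcl11b, a T cell lineage factor, had 1013 reads against 107, a ratio of 4.62 (3.78 to 5.69). Ikzf1, the gene of the lymphoid factor Ikaros, had 370 against 13, a ratio of 13.9 (8.01 to 26.3). Ets1 had 203 reads, on 12 circRNAs, against 0. Tox did not pass, at 62 against 18, a ratio of 1.68 (0.981 to 3.02). Elmo1 went the other way, at 30 against 29, a ratio of 0.504 (0.2925 to 0.871) that missed the 2-fold rule. Inpp5d and Itgae, each at 7 against 4, did not pass either. The stromal, muscle and endothelial list had a summed ratio of 18.7 (11.9 to 31.2), but 649 of its 728 reads labelled ISC came from Zeb1, which lymphocytes also express, and 67 from Pecam1. Without Bcl11b the immune list's ratio was 10.4, and over circRNAs with reads in both libraries it was 6.09.

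**Figure D2:**
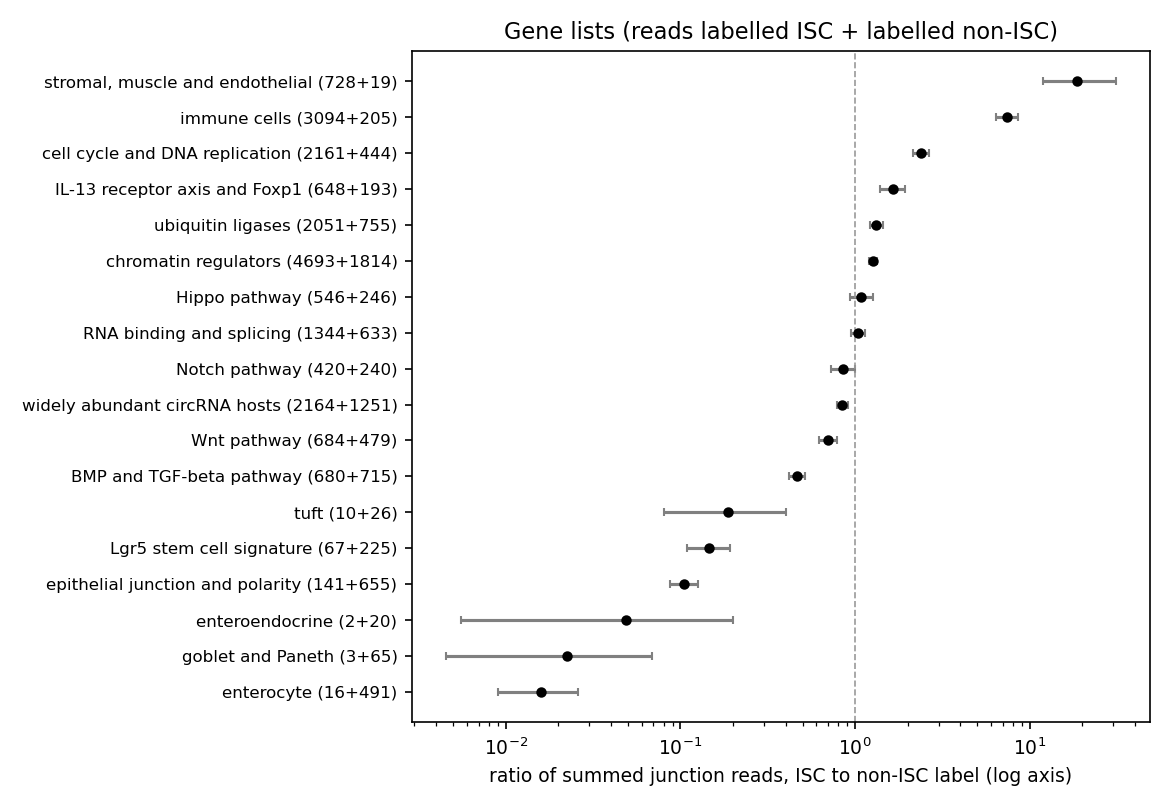
Ratio of summed junction reads of each of the fixed gene lists with reads in both libraries, labelled ISC over labelled non-ISC (log axis), with 95% exact counting intervals as bars; reads of both libraries stand in brackets and the dashed line marks 1. The lists run from enterocyte genes at 0.0159 to stromal, muscle and endothelial genes at 18.7.

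Of 29 genes of cell division with at least 10 reads, 13 were higher in the library labelled ISC, 0 were lower and 16 did not pass, with a summed ratio of 2.37 (2.14 to 2.63) at percentile 98.7. The percentile was 92.7, inside the random range, with a minimum of 50 reads and over single circRNAs. Bub1b had 679 reads against 55 (ratio 6.02, 4.57 to 8.07), but 630 of the 679 were on the circRNA with no entry in the library labelled non-ISC, so this ratio rests on that entry standing for 0 reads. Also higher were the topoisomerase gene Top2a, at 128 against 19 (ratio 3.28, 2.02 to 5.63), and Atad2, at 110 against 10 (ratio 5.36, 2.81 to 11.5). Ckap5 had 230 against 63 and Cep192 130 against 42, ratios of 1.78 (1.34 to 2.39) and 1.51 (1.06 to 2.19) that missed the 2-fold rule. Over circRNAs with reads in both libraries the list's ratio was 1.26. Chromatin regulators gave 1.26 (1.19 to 1.33), with 13 of 47 higher and 1 lower. Ezh2, the Polycomb methyltransferase gene, had 437 against 63 (ratio 3.38, 2.59 to 4.48), while Ehmt1 had 482 against 228 (ratio 1.03, 0.879 to 1.21). Ubiquitin ligases gave 1.32 (1.22 to 1.44), with 8 higher and 3 lower of 30. Fbxw7 was at 342 against 78, a ratio of 2.14 (1.67 to 2.77). Both lists lay inside the range of random lists, at percentiles 81.2 and 95.6.

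Of the signalling lists, Wnt, Hippo and Notch held genes higher and genes lower in the library labelled ISC. The Wnt list gave 0.696 (0.619 to 0.784), turning to 1.96 with library totals, with 3 of 16 genes higher and 3 lower. Ctnnb1, the gene of beta-catenin, had 42 reads against 57 and Lrp5 56 against 70, while Tcf7 and Lef1, factors also of T cells, had 32 and 20 reads against 0. The BMP and TGF-beta list gave 0.464 (0.417 to 0.516), turning to 1.31 with library totals, with 3 of 10 lower and 0 higher. Acvr2a had 21 against 88 (ratio 0.116, 0.0686 to 0.189), Smad1 130 against 168 and Smad4, which missed the rule, 386 against 368. In the Hippo list 4 of 15 were higher, such as Stk4 at 132 against 30, and 4 lower, such as Yap1 at 2 against 9. Its summed ratio was 1.08 (0.929 to 1.26). The Notch list gave 0.853 (0.726 to 1.004), turning to 1.05 with median-ratio scaling and 2.40 with library totals, with Numb lower at 12 against 25 and Maml2 higher at 13 against 0. RNA binding and splicing genes gave 1.04 (0.941 to 1.14), 6 of 21 higher and 4 lower; Esrp1, an epithelial splicing regulator, had 4 against 57 and Cpsf6 230 against 46. Hosts known for abundant circRNAs in many tissues gave 0.843 (0.786 to 0.905), turning to 1.07 without Elf2 (555 against 515), 1.04 with median-ratio scaling and 2.38 with library totals. The Wnt, BMP and TGF-beta, Hippo, Notch, RNA binding and abundant-host lists lay at percentiles 26.6, 12.3, 75.9, 25.1, 63.0 and 51.3 of random lists.

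Pan3, a subunit gene of the PAN2-PAN3 deadenylase and the host gene the study is known for, was higher in the library labelled ISC. The gene lies on chromosome 5 (147430161 to 147548502, GRCm38) and had 360 reads on 23 circRNAs there, against 42 reads on 7, a ratio of 4.18 (3.03 to 5.90). The most abundant circRNA ran from 147450653 to 147488258, the outer ends of exons 2 and 5 of the transcript used for exon numbers, with a spliced length of 408 nt. It had 198 reads against 22, a ratio of 4.39 (2.82 to 7.16). Next came 147450653 to 147503202, with 52 against 4 (ratio 6.34, 2.33 to 24.1), and 147450653 to 147467097, with 45 reads and none listed in the library labelled non-ISC. These 3 were the Pan3 circRNAs with at least 10 reads, and all were higher. Below that minimum, the one at 147488111 to 147503202 went the other way, with 1 read against 8 (ratio 0.0609, 0.00137 to 0.4545). Over Pan3 circRNAs with reads in both libraries the ratio was 3.275. Which Pan3 circRNA matches the one named in the study was not settled from the sources used here. In the list of Pan3, Foxp1 and the IL-13 receptor axis, Jak1 was higher (19 against 2), Stat6 lower (22 against 27) and Foxp1 at a ratio of 0.942 (0.752 to 1.19). The list's summed ratio was 1.64 (1.39 to 1.93), with its median at percentile 90 of random lists. Without Pan3 these were 0.930 and 71.5. The immune list, at 7.36, moved the same way as Pan3 between these libraries.

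**Figure D3:**
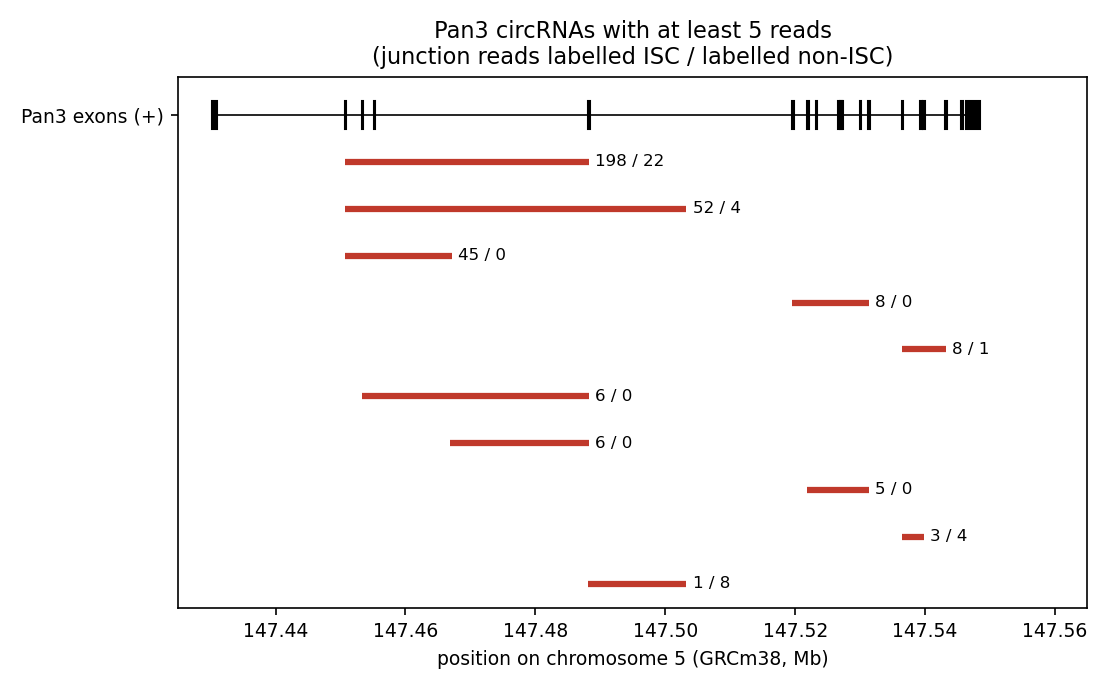
The 10 Pan3 circRNAs with at least 5 reads (red bars, from start to end of the circle) under the 19 exons of the transcript used for exon numbers (black), by position on chromosome 5 in Mb, with junction reads labelled ISC and labelled non-ISC at the right. The 3 most abundant share the start at 147450653 and have 198, 52 and 45 reads labelled ISC against 22, 4 and 0; some ends lie on exons of other transcripts.

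Both junction ends lay on exon ends of 1 annotated transcript for 72.6% (71.9 to 73.2) of the circRNAs labelled ISC and 75.1% (74.4 to 75.9) of those labelled non-ISC, holding 88.0% and 88.4% of reads. Among circRNAs with at least 10 reads in the library the shares were 92.6% (91.5 to 93.6) and 93.9% (92.5 to 95.1). Ends inside a gene but on no exon end were found for 14.1% and 11.7%, and circRNAs outside genes for 0.689% and 2.25%. The median genomic span was 4910 nt (quartiles 1337 and 12606) and 5642 nt (quartiles 1668 and 13833). Exonic circles held a median of 3 exons in both, with spliced lengths of 457 and 494 nt. The mitochondrial chromosome gave 1 circRNA in the library labelled ISC and 54 in the library labelled non-ISC.

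The last comparison asked whether host genes used the same circRNA in both fractions. Of 199 host genes with at least 50 reads in each library, 153 (76.9%) had the same leading circRNA. In 24 of the other 46, the shares of both leading circRNAs had separate intervals, and in 12 of these both had reads in both libraries. In Kat6b, a histone acetyltransferase gene, the circRNA at 21626719 to 21637640 on chromosome 14 held 60.8% (55.6 to 65.9) of the gene's 360 reads labelled ISC and 15.6% (10.04 to 22.7) of its 141 labelled non-ISC. The one at 21516626 to 21517498 held 28.9% (24.3 to 33.9) and 68.1% (59.7 to 75.7). Foxp1 and Crebbp were also among the 12. In the remaining 12 such genes, Bub1b, Tns3 and Usp3 among them, a leading circRNA had no listed reads in 1 library.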

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

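Tests of the T lineage, epithelial transcription factor and keratin and adhesion lists and of junction ends within 5 nt were set before their results were seen. The other tests in this part, values with library totals and the use of the transcription factor list against Lgr5-expressing epithelial cells were chosen after the result was seen.

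Outside the junction reads, an entry placed in Rpph1 led the deposited count column of each library, with 79.1% of it for the label ISC and 25.5% for the label non-ISC. Rpph1 is the gene of the RNase P RNA. In the library labelled ISC the entry (chromosome 14, 50807452 to 50807756) had 8348944 reads, 15.9% of that library's total, with 3 junction reads. In the library labelled non-ISC a different entry, with the same start and its end at 50807731, had 803144 reads, 1.11% of the total, with 0 junction reads. That list also held 6122 circRNAs with 0 junction reads and a count above 0 (median 19), and the list labelled ISC had no such entry.

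Lymphoid host genes were high and epithelial ones low in the library labelled ISC, a pattern the sort on Lgr5-GFP would not be set to give. Lgr5-expressing epithelial cells alone would leave keratin and adhesion genes, listed as shared by stem and differentiated epithelium, within 2-fold. Their ratio was 0.202 (0.168 to 0.242), although with library totals it was 0.568 (0.472 to 0.681), within what this explanation allows. That list was written after junction genes had been seen to be low, and it shares Vil1 with the enterocyte list (0.204 without Vil1). It therefore extends the low epithelial genes and is no separate test beside them. Epithelial transcription factor genes had 0 reads against 54, with an upper bound of 0.0971 with library totals. Under either scaling they argue against Lgr5-expressing epithelial cells alone only if missing entries stand for 0 reads. No gene of that list had reads in both libraries, and 3 had at least 10 reads. Lymphoid cells in that library may account for the pattern: a T lineage list holding no gene seen before had a ratio of 3.73 (3.01 to 4.68). Its median was at percentile 96.4, inside the range of random lists, and 11 of its 24 genes with a circRNA had reads in both libraries. Most of its 720 reads labelled ISC came from Prkcb (245 reads against 13) and Nfatc3 (185 against 24). Without Prkcb the ratio was 2.86 (2.25 to 3.67). The ratio thus rests on few genes, and whether those mark T cells alone was not tested. An exchange of the labels cannot be told apart. The Lgr5 signature (0.145) goes that way, but it lies between the junction (0.105) and keratin and adhesion (0.202) lists. It is thus no separate sign of an exchange beside the low epithelial genes. Enterocyte genes at 0.0159 go against an exchange unless the Lgr5-negative sort held hardly any epithelium, which the labels do not say. Their ratio rests on missing entries counted as 0. A difference between Lgr5-positive and Lgr5-negative cells as such stays open and untested, with 1 library each.

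Numbers of circRNAs with 2, 4 or 6 junction reads were at least 1.31 times the geometric mean of the numbers with 1 read fewer and 1 more, in each library. In the library labelled ISC 4636 had 1 read, 5425 had 2, 1323 had 3 and 1944 had 4, and in the library labelled non-ISC 3803, 3190, 1049 and 1100. Counting of both mates of a pair stays open, since the 1.31 restates the pattern and no separate test of it was made. Spurious junctions of 1 or 2 reads are argued against as the whole cause, since among circRNAs with both ends on exon ends the value for 4 reads was 1.79 in the library labelled ISC. No biological explanation was tested.

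Of 262 circRNAs with at least 60 reads in 1 library whose host gene had at least 20 other reads in the other, 17 had no entry in that other library. Junction ends placed a few nt apart are argued against for most, as 11.8% of the 17 had a partner within 5 nt. Missing entries and true absence cannot be told apart, since 17 without an entry stand beside 14 with 1 to 10 reads. The balance differed by library: 10 without an entry and 1 with few reads among circRNAs abundant in the library labelled non-ISC, and 7 and 13 among those abundant in the library labelled ISC. A real exchange of circRNAs between the fractions stays open.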

How the results depend on the processing

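Scaling to library totals, halved reads, lists over circRNAs with reads in both libraries and alternatives for added lists were chosen after seeing the data; the cause of a move was not tested unless stated. Median-ratio and TMM scaling shift log2 ratios by 0.30 and 0.27 and library totals by 1.49, and leaving out the 10 most abundant circRNAs shifts them by -0.0026. For circRNAs the numbers higher and lower, 1187 and 841, became 2140 and 426 with library totals, 595 and 431 at 20 reads, 398 and 513 with reads in both libraries and 472 and 355 with halved reads. The lower number became 1626 at 5 reads and 2306 with no minimum, and the higher number 733 with a 99% interval. With no minimum, 10 reads against 0 are by construction needed to count as higher and 4 to count as lower. Under the main rule at least 10 are needed either way. For host genes, 779 and 663 became 1717 and 324 with library totals and 438 and 416 with halved reads. The lower number was 1041 with no minimum, and the higher one 475 with reads in both. The other settings kept these counts within 1.5 times.

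The share of circRNAs in both libraries, 16.7%, was 22.5% at 2 reads in either, 47.1% at 5, 17.3% after thinning and 46.7% by host gene. It rises with the minimum because circRNAs with few reads are dropped. The share with both ends on exon ends was 76.6% at 2 reads and 92.6% at 10 for the label ISC, and 81.1% and 93.9% for the label non-ISC. A limit on spans of 100 kb removed nothing.

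With library totals the summed ratio was 0.409 for the Lgr5 signature, 0.0447 for enterocyte, 20.7 for immune, 6.68 for cell cycle and 0.296 for junction genes, and 11.8 for Pan3. It turned to 1.96 for Wnt, 2.40 for Notch, 1.31 for BMP and TGF-beta, 2.38 for widely abundant hosts 1.12 for the Rbm4 circRNA and 2.70 for the Rasa2 circRNA. With the median ratio it was 9.06 for immune, 2.92 for cell cycle, 0.129 for junction genes and, turned, 1.04 for abundant hosts, 1.05 for Notch and 1.18 for the Rasa2 circRNA (1.15 with TMM). Over circRNAs with reads in both libraries it was 0.307 for the Lgr5 signature, 6.09 for immune, 1.26 for cell cycle and 0.240 for junction genes. Without the member with the most reads it was 10.4 for immune and 1.86 for cell cycle, and it turned to 0.930 for the IL-13 list and 1.07 for abundant hosts. Among added lists the myeloid ratio turned to 2.47 without Mertk and 1.13 with library totals, B lineage to 0.853 without Ralgps2, and both together, 0.430 without Ralgps2, to 1.79 without Mertk and 2.26 with library totals. Of 69 alternative list medians, 67 kept their side of the random range. The 15 with median-ratio scaling could not change it, as that scaling shifts random lists alike. The cell cycle list fell inside the random range at a minimum of 50 reads and over single circRNAs (percentile 92.7 under each). So 1 list in place of 2 lay above random lists under each of these, and 1 in place of 4 below at 50 reads, where 11 lists could be scored. Of 49 alternatives for named ratios, 36 stayed in the main interval.

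No paired analysis was possible because each group has 1 library.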

Other observations

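Except for the T lineage, B lineage, myeloid, epithelial transcription factor and keratin and adhesion lists, whose tests were set before their results were seen, the values in this part were chosen after the libraries had been examined. Tests with genes left out were among those chosen after, and the rule for the verdict on blood lineages was changed after its values were seen.

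Early T cell genes were among the added lists. Thymocyte genes had 105 reads in the library labelled ISC against 4, a ratio of 12.8 (4.85 to 47.8). Dntt and Rag1, which act in antigen receptor gene assembly, had 35 and 22 reads, on 7 and 12 circRNAs, and Tdrd5 had 33, each against 0. In the cytotoxic T and NK list Cd160 alone had reads, 0 against 2. Epithelial transcription factor genes had 0 reads in the library labelled ISC against 54, with Grhl2 at 17, Gata6 at 12 and Nr5a2 at 11. Of 9 keratin and adhesion genes with at least 10 reads, 8 were lower, such as Erbb3 at 0 against 38 and Ocln at 2 against 30.

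A hypothesis that blood cells of all lineages were present alike was tested with B lineage and myeloid genes. The B lineage list alone had a ratio of 1.61 (1.20 to 2.19), led by Ralgps2 at 181 against 51, and 0.853 (0.334 to 2.35) without it. Both lie below the lower bound of 3.01 of the T lineage list. However, the first rests mostly on Ralgps2, which had many reads in both libraries, and the second on 14 reads against 8. An equal share of B lineage cells therefore stays open. The myeloid list gave 0.402 (0.304 to 0.529), led by Mertk at 22 against 104, but turned to 2.47 (1.41 to 4.63) without Mertk. That interval overlaps the T lineage list's, so an equal share of myeloid cells stays open. Together the lists gave 0.802 (0.664 to 0.972), and from 0.430 (0.330 to 0.559) without Ralgps2 to 1.79 (1.38 to 2.34) without Mertk with any 1 gene left out, also below that bound. Without Prkcb the T lineage list was at 2.86 (2.25 to 3.67), which overlaps the sum without Mertk and the B lineage list without Ralgps2. No verdict on blood lineages is therefore drawn from these lists. Mrc1, a macrophage gene, had 18 reads against 0.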
